A study of Meyerozyma caribbica with 2 samples.

How the data were processed

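Transcripts of the yeast Pichia caribbica (Meyerozyma caribbica) were measured by RNA sequencing in 2 cultures. Per the labels' protocols, cells were grown for 20 h at 28 °C in the dark in NYDB medium with shaking at 180 rpm. They were then held for 40 min in the same medium with H2O2 or with distilled water, and total RNA was extracted and made into Illumina TruSeq libraries. The H2O2 concentration is not given in the sources used here. The control group and the H2O2 group each hold 1 library, taken from the treatment labels.

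Per the file headers, the authors deposited for each library an expected count, a TPM value (transcript abundance corrected for length), a length and an effective length for 5166 unigenes, which are assembled transcripts grouped as genes. The unigene identifiers carry the prefix of the Trinity assembler, and the column names of the deposited tables are those of an RSEM gene table. Bowtie 0.12.2 is named in the submitters' processing notes, without its role. An expected count in the deposited tables need not be whole, because reads that match several unigenes are divided between them. The control library summed to 14699850 counts and the H2O2 library to 18358209. Of the unigenes, 23.2% in the control library and 26.0% in the H2O2 library had a count that was not whole within 0.005, so divided reads touch many values. The authors also deposited a comparison table with a log2 ratio and an FDR (a p-value adjusted for multiple tests), per the file headers, for 998 unigenes together with protein annotation. The test and the scaling behind that log2 ratio and FDR are not given in the sources used here. A further deposited file gave predicted coding sequences for 5162 unigenes. No genome was used, so no chromosome positions are given.

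The expected counts were rounded to whole numbers. Library sizes were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 0.8875 for control and 1.1267 for H2O2. The log2 ratio of H2O2 over control was computed after adding 0.5 counts to each library. The 95% interval of each ratio is the exact conditional binomial (Clopper-Pearson) interval. It covers counting error only, since each group has 1 library. It treats reads as independent molecules, which reads without molecular identifiers are not, and takes no account of divided reads, so it can be too narrow. A unigene was called higher or lower when it had at least 20 counts over both libraries, differed at least 2-fold and had an interval that excluded equality. With 1 library per group no residual degrees of freedom remain, so there is no replicate check, no test between conditions and no p-value. A count of 0 allows up to 3 counts, a CPM of 0.230 in the control library and 0.145 in the H2O2 library. Ratios against a library at 0 are therefore printed as "at least" a fold, computed against 3 counts in that library.

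Before the data were examined, 29 gene lists, the rule for named genes and the alternatives were fixed. Lists were matched to protein names, so some members do not do what the name of their list says, and the lists were also run without these members. Only unigenes in the authors' deposited table carry names, so the background of the lists is the 958 of them with 20 or more counts, whose median log2 ratio was -2.30. All of these had been selected by the authors as different between the same libraries, so a list's direction is not independent of that selection and members outside the table were not seen. For each list the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 10 groups, and a list was said to stand apart below percentile 2.5 or above 97.5. This describes these 2 libraries. Named genes were the 12 highest and 12 lowest named unigenes with at least 100 counts, up to 4 members per list with the largest absolute log2 ratio and at least 100 counts, and the antioxidant genes the annotation names. That gave 109 unigenes.

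Unigenes with near-identical coding sequences (98% identity over 80% of the shorter) were found with BLAST 2.17.0 at an e-value of 1e-20. Counts were also summed over assembly components, which are unigenes whose identifiers share all but the last part. A component can join overlapping pieces of one gene, neighbouring genes or copies. Unigenes were sorted by the organism of their best database hit. Codon usage was scored as the mean log frequency of synonymous codons, with frequencies from 436 yeast unigenes, and compared with the 50 nearest by length of 4613 other unigenes without animal or plant hits. Alternatives were DESeq2 1.42.0 size factors, total counts, the deposited TPM, other count minimums, prior counts and fold sizes, a mean for the list median, and counts summed over the same best hit. Sums over near-identical sequences or components, whole counts only, restriction by best-hit organism, and lists without members of another function were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

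The calculation was tested on simulated data for the H2O2 over control comparison, run on 3603 unigenes with 200 changed. Of 100 unigenes changed 2-fold, 50 were called, with a median log2 ratio of 1.00. A change of exactly 2-fold lies on the limit of the call, so a share near 50% follows from the rule. Of 100 changed 4-fold, 99 were called, with a median of 2.00. Of 3403 unchanged unigenes, 11 (0.32%) were called. Simulated counts carried counting error only, were not divided between unigenes, and had as many unigenes changed upwards as downwards. In the data 2004 unigenes were called and many counts were divided. These rates therefore leave out differences between cultures, the division of reads and errors of scaling.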

Results

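The series compared RNA from Pichia caribbica cells held for 40 min with H2O2 and from cells held without it, to describe the transcript response of this yeast to peroxide. Each condition had 1 library, with 14699850 counts in control and 18358209 in H2O2. No difference given here has a replicate check, and all intervals cover counting error only. Of 5166 unigenes, 1457 had no counts in control and 658 had none in H2O2. The 10 most abundant unigenes took 21.7% of control counts and 13.6% of H2O2 counts.

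The main question was which transcripts differed after H2O2. In the H2O2 library the subunits of the proteasome, the complex that degrades ubiquitin-tagged proteins, were higher as a group, with a median log2 ratio of 2.87 over 15 of 15 named unigenes. Proteins of the cytosolic ribosome were lower, with a median of -6.68 over 63 of 63 unigenes with yeast best hits. Ribonucleotide reductase RNR1, which makes DNA precursors, was 27.8-fold higher. The ferric reductase FRE7 went from 15821 counts in control to 21 in H2O2. Catalase CTT1, which breaks down H2O2, was 6.99-fold lower, whereas glutathione reductase GLR1 was 4.93-fold higher.

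Across the 3595 unigenes with at least 20 counts, 975 (27.1%) were at least 2-fold higher in H2O2 and 1029 (28.6%) at least 2-fold lower, while 1591 met neither rule. The log2 ratios had a standard deviation of 2.90, with quartiles of -1.24 and 1.12 around a median of 0.04. Higher calls made up 48.7% of all calls with TMM scaling, 59.6% with total counts and 67.5% with the deposited TPM. Total counts moved the median of all unigenes by 0.34 and TPM by 0.61 on the log2 scale, so ratios are given relative to the TMM-scaled libraries.

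**Figure D1:**
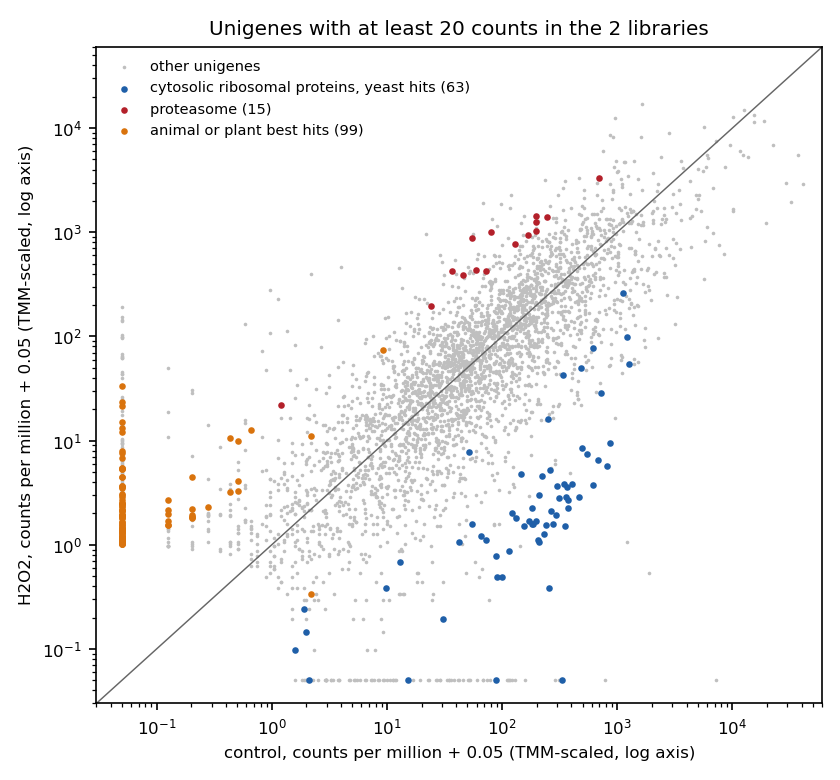
Scaled CPM of each unigene with at least 20 counts in the control library (horizontal, log axis) and the H2O2 library (vertical, log axis), with 0.05 added so that zeros can be drawn. Points are unigenes and the line marks equality, with the 15 proteasome unigenes above it and the 63 yeast ribosomal protein unigenes under it. Most of the 99 unigenes with an animal or plant best hit lie at the left edge, at few or no control counts.

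Proteasome transcripts together had 28737 counts in control and 288657 in H2O2. The regulatory subunit 4 homolog (TRINITY_DN431_c0_g1) was 16.2-fold higher, at log2 4.01 (95% interval 3.91 to 4.13). Regulatory subunit 6A was 12.4-fold higher and the proteasome component ECM29 was 11.7-fold higher. The list's median lay at percentile 99.9 of random lists, with a median of 2.61 for component sums. Among ubiquitin genes 8 of 8 were higher, with a median of 3.88 at percentile 99.1, including 1 with an animal best hit and ATG7, an enzyme of autophagy. Without ATG7 the median was 3.91 at percentile 97.8. The ubiquitin ligase dbl4 had 133 counts in control and 3189 in H2O2, a log2 ratio of 3.91 (3.67 to 4.18), and the deubiquitinating enzyme of TRINITY_DN2307_c0_g3 had 85 and 1958, a log2 ratio of 3.85, or 2.24 with its component. With component sums the ubiquitin median was 1.87 at percentile 91.8 and no longer stood apart. TOM1 and UBA1, at 0 in control, came to -0.28 and 0.48 in those sums.

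Autophagy genes, which serve bulk degradation in the vacuole, were higher in 4 of 4 unigenes, with a median of 2.89 at percentile 94.5, or 1.602 with component sums. ATG8, the ubiquitin-like protein of the autophagosome membrane, was 7.77-fold higher (4431 counts against 54610), or 4.15-fold with its component. ATG22 was 5.72-fold higher, and ATG2, at 0 in control, was 1.04-fold higher as a component. Peroxisome and fatty acid oxidation genes were higher in 6 of 7 unigenes, with a median of 2.36 at percentile 84.3, or 1.04 with component sums. After merging near-identical copies 4 of 6 were higher and 1 lower. PEX5, the import receptor of peroxisomal enzymes, was 16.6-fold higher, and PEX30 was 7.33-fold lower. The acyl-CoA oxidase POX1 had 0 counts in control and 2145 in H2O2, yet its component sum differed by a log2 ratio of 0.68. Summed with its near-identical copy only, it had 1695 counts in control and 14272 in H2O2, a log2 ratio of 2.41.

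Cytosolic ribosomal protein unigenes numbered 77 with enough counts, and their median log2 ratio was -6.19 (-6.14 with zeros at their bound), below all random lists. The 14 members that were higher all had an animal or plant best hit, whereas the 63 with yeast hits were all lower. RPL22B had 1158 counts in control and 0 in H2O2, at least 612-fold lower, and its component sum was 237-fold lower. The S14-A protein was at least 105-fold lower and the S26-A protein was 748-fold lower, or 18.8-fold with its component. RPL17, from 4289 counts to 0, had a component log2 ratio of -0.88. Mitochondrial ribosomal proteins were lower in 18 of 21 unigenes, with a median of -3.04 at percentile 17.8, as in MRPS18 with 167 counts against 6. Ribosome biogenesis genes were lower in 7 of 9, with a median of -4.13 at percentile 5.2 and -1.27 with component sums. RPA190, the large subunit of RNA polymerase I, was 17.8-fold lower and TSR1 17.8-fold lower. The summed counts of the list went the other way, from 17527 to 103525, mostly through UTP20 (named after its values were seen), which was 5.05-fold higher with 12612 counts against 100974.

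Named antioxidant genes were few, because the authors' deposited table names only selected unigenes. The scavenging list held 3 unigenes, 2 higher and 1 lower, with a median of 2.59 (2.07 with zeros at their bound, percentile 51.4). CTT1 had 13658 counts in control and 3099 in H2O2, a log2 ratio of -2.80 (-2.86 to -2.75). The cell surface superoxide dismutase SOD6 had 7 and 71 counts, a log2 ratio of 2.59 (1.56 to 4.04). A PRX1 peroxiredoxin unigene with 0 and 20 counts had an animal best hit. In the thioredoxin and glutathione list 2 of 2 were higher, with a median of 2.85 at percentile 69.8, or 1.77 with component sums. GLR1, which regenerates glutathione, had 2394 and 18721 counts, a log2 ratio of 2.30 (2.24 to 2.36). Mitochondrial glutaredoxin-2 had 6 and 108 counts, and 2.36-fold more in H2O2 after summing its component.

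Among old yellow enzymes and aldehyde dehydrogenases 2 were higher and 3 lower, with a median of -2.59 at percentile 24.4, or -1.67 with component sums. One of the lower unigenes is a phosphopantetheinyl transferase of lysine synthesis that was matched by name, and without it 2 were higher and 2 lower, with a median of 0.56 at percentile 70.9. The potassium-activated aldehyde dehydrogenase (TRINITY_DN3593_c0_g1), a mitochondrial enzyme that oxidises acetaldehyde, was 13.0-fold higher (12401 counts against 255803). The NADPH dehydrogenase EBP1 was 8.16-fold and 6.01-fold lower in 2 unigenes, the former 3.17-fold lower with its component. Pentose phosphate genes, which supply NADPH, were lower in 2 of 2, with a median of -7.32 (-6.03 with zeros at their bound, percentile 6.1), but -0.78 at percentile 43.0 with component sums. SOL3 was 7.01-fold lower, while RPE1, at 0 in H2O2, came to a log2 ratio of 1.24 with its component. Stress signalling held 1 unigene, RIM9 of pH sensing, with 0 counts in control and 21 in H2O2 (percentile 23.8) and a log2 ratio of 0.98 as a component.

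Heat shock proteins and chaperones were lower in 7 of 10 unigenes, with a median of -2.33 at percentile 48.3. Of the 7, VTC2 and VTC4 are subunits of the vacuolar polyphosphate polymerase that were matched by the word chaperone, and HSP31 is named a glyoxalase. Without the VTC unigenes 5 of 8 were lower, with a median of -2.22 at percentile 49.2. The chaperone SSA1 had 110109 counts in control and 12656 in H2O2, a log2 ratio of -3.79 (-3.81 to -3.76), or -3.17 with its component. HSP104, a disaggregase, had 94349 counts in control and 0 in H2O2, and its component was 5.89-fold lower. Trehalose synthesis genes were lower in 3 of 3, with a median of -2.81 at percentile 28.0. TPS1 was 7.65-fold and 7.01-fold lower in its 2 unigenes and TPS3 was 6.80-fold lower.

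Genes of energy metabolism with yeast hits were mostly lower. In the respiratory chain list 22 of 24 yeast unigenes were lower, with a median of -3.24, and 16 of 16 with animal or plant hits were higher. All 40 together had a median of -2.35 at percentile 22.7 and a mean of 1.15, and yeast unigenes alone stood at percentile 0.37. Tricarboxylic acid cycle genes were lower in 5 of 5, with a median of -2.60 at percentile 33.8. IDH2 was 17.5-fold lower and ACO1 6.08-fold lower, whereas FUM1, 5.12-fold lower, had a log2 ratio of 0.48 with its component. Glycolysis split into 6 yeast unigenes, all lower with a median of -2.75, and 6 with animal hits, all higher, so the median of 12 was 0.40 (0.06 with zeros at their bound, percentile 54.4) and 3.24 with component sums. The aldolase FBA1 was 23.1-fold lower (9.24-fold with its component), PYK1 11.9-fold (5.67-fold) and PDC11 6.97-fold lower.

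Iron acquisition was lower in 6 of 6 unigenes, with a median of -3.13 at percentile 9.5. FRE7 had a log2 ratio of -10.19 (-10.91 to -9.61), the siderophore transporter mirB was 10.9-fold lower, the permease FTR1 10.2-fold and the oxidase FET3 7.49-fold. Sulfur and methionine genes were lower in 4 of 4, with a median of -3.73 at percentile 12.8, or -2.38 with component sums. MET6 was 24.7-fold and 4.41-fold lower in 2 unigenes, or 5.2-fold as a component, and sam1 was 8.94-fold lower. Amino acid synthesis genes were lower in 8 of 9, with a median of -4.00 at percentile 8.6, but -2.35 at percentile 34.4 with component sums. One of the 8 is a dioxygenase of NAD synthesis, and without it the median was -4.51 at percentile 6.4. OTC and ARG5,6 of arginine synthesis were 38.9-fold and 32.7-fold lower, and ILV5 was 16.1-fold lower, while ARG1, at 0 in H2O2, had a log2 ratio of -0.57 as a component. Ergosterol and lipid synthesis genes were lower in 11 of 13, with a median of -4.02 at percentile 2.47, but -2.43 at percentile 27.2 with component sums, and the list stood apart under 5 of 11 other settings. The 2 higher unigenes are both Sterol uptake control protein 2, a transcription factor, and without them 11 of 11 were lower, with a median of -4.21. The Delta(12) fatty acid desaturase was 36.4-fold lower and the fatty acid synthase unigene FAS1 22.8-fold lower.

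DNA repair genes were higher in 4 of 6 unigenes, with a median of 3.45 at percentile 97.6 (3.19 with zeros at their bound). RNR1 had 890 counts in control and 39231 in H2O2, a log2 ratio of 4.80 (4.70 to 4.90), and the base excision enzyme APN1 was 5.49-fold lower. CMR1 appeared in 2 unigenes at log2 ratios of 5.70 and -3.37, which summed to -2.93, and with component sums the list's median was 0.80 at percentile 80. The list stood apart under 5 of 11 other settings. It did not with at least 100 counts, a prior count of 5, whole counts only, a mean, or sums over best hits or components. Cell cycle genes were higher in 8 of 10, with a median of 2.64 (2.59 with zeros at their bound, percentile 81.7) and 0.61 with component sums. The origin recognition subunit 2 was 9.63-fold lower. The kinetochore gene NDC80 gave log2 ratios of 2.66 and -3.19 in 2 unigenes and 1.10 in sum, and DPB2, at 2.74, had -0.07 in sum.

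The list of drug transporters took in 12 unigenes by name, with a median of -2.37 at percentile 55.0, or -0.32 with component sums, but 5 of them are not transporters. These are 4 unigenes of Multidrug resistance regulator 1, a transcription factor, all higher, and ARB1 of ribosome biogenesis, which was lower. Of the other 7 unigenes 6 were lower and 1 higher, with a median of -3.22 at percentile 12.8. The higher one, Multidrug resistance protein 1 (named after its values were seen), had 3237 counts in control and 29668 in H2O2, and brought the sum of the 7 to 14754 and 31782. CDR1, a drug efflux pump, was 19.7-fold lower and the polyamine transporter TPO1 was 14.2-fold and 9.35-fold lower in 2 unigenes. One unigene of the regulator was 27.6-fold higher, with 7 and 306 counts, or 1.65-fold as a component. The more abundant TRINITY_DN2384_c0_g1 and TRINITY_DN1359_c0_g1 (named after their values were seen) were 4.94-fold and 6.68-fold higher, each alone in its component. Sugar transporters with yeast hits were lower in 2 of 2, STL1 by 5.16-fold and RGT2 by 5.03-fold, while 1 animal hit, the enzyme xylose reductase, was higher, so the list had a median of -2.33 and a mean of 0.44 (percentile 39.3). Cell wall genes were divided 15 to 15, with a median of 0.07 (-0.05 with zeros at their bound, percentile 83.5). Of these unigenes 9 were at 0 in a library, and the median was -1.39 at percentile 29.5 with component sums and -2.18 when summed over the same best hit. Their 29 yeast unigenes had a median of -2.17. Without BCR1, a transcription factor, 14 of 29 were higher and the median was -2.17 at percentile 71.8. Chitin synthase CHS2 had 0 counts in H2O2 in 2 unigenes and was 2.47-fold lower as a component.

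**Figure D2:**
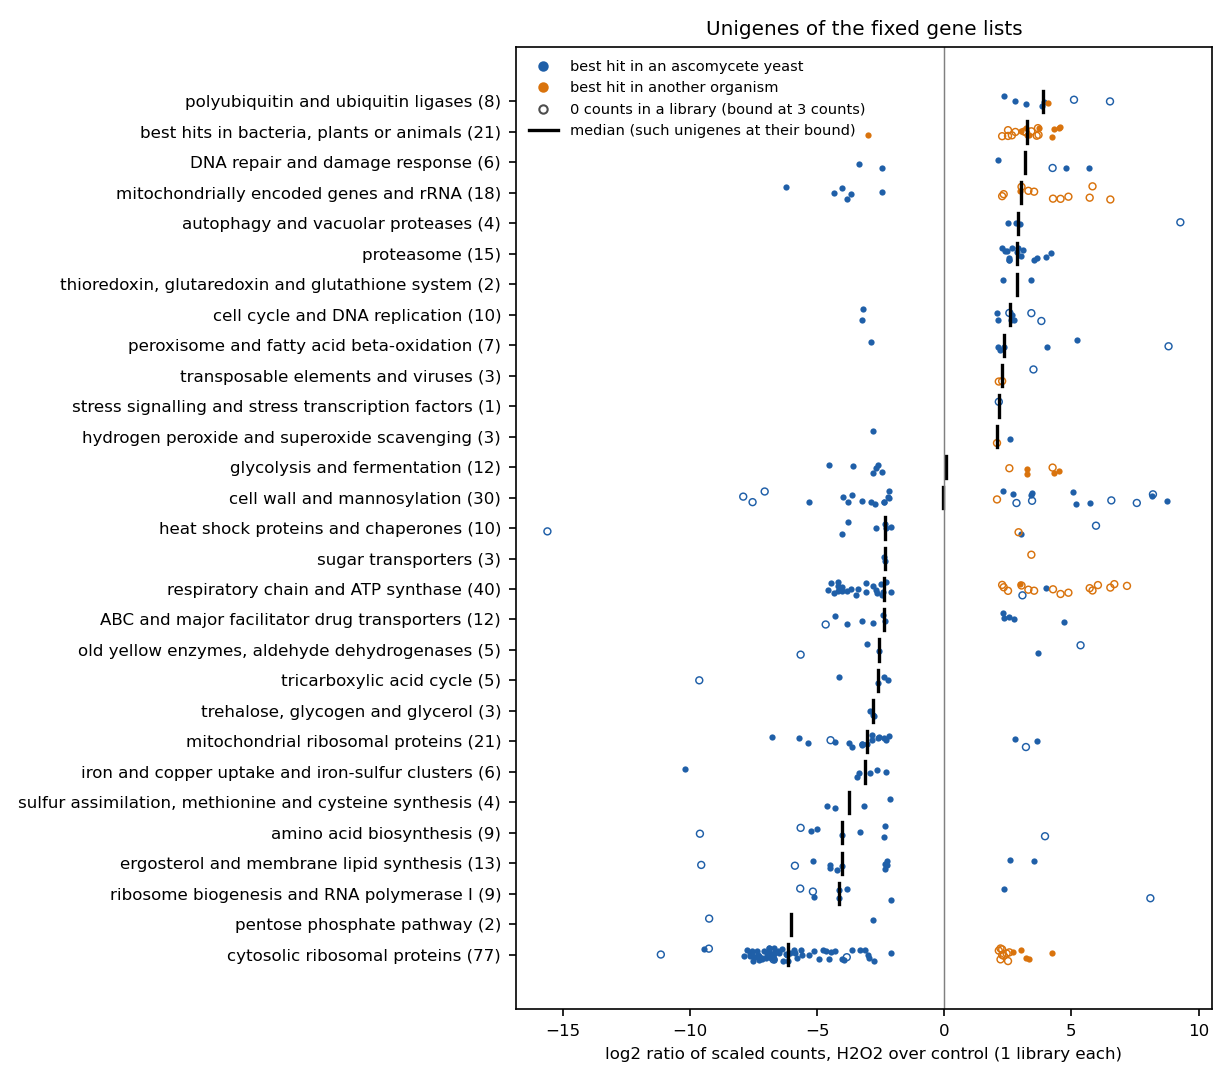
Log2 ratio of H2O2 over control (horizontal) for each unigene with at least 20 counts in the 29 gene lists (vertical, number of unigenes in brackets), with 1 library per condition. Blue points have a best hit in an ascomycete yeast and orange points in another organism, open points are at 0 in a library and drawn at the bound from 3 counts, and bars are medians. Proteasome points are all right of 0, and ribosomal protein points split by organism.

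The unigenes with the most extreme ratios were mostly those at 0 in a library. Of the 12 highest, 12 had 0 counts in control, among them FRS1 (phenylalanine tRNA ligase), at least 839-fold higher, ATG2, at least 622-fold, and the alpha tubulin TUB1, at least 431-fold. After summing components their folds were 1.33, 1.04 and 1.20. Of the 12 lowest, 11 had 0 counts in H2O2, among them the transcription factor GCN4, at least 5381-fold lower but 2.33-fold lower as a component. The exception was a COBW domain protein (SPBC15D4.05), alone in its component, with 24778 counts in control and 10 in H2O2, a log2 ratio of -11.87 (-13.00 to -11.06). In all, 20 of the 24 had a component sum within 4-fold.

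**Figure D3:**
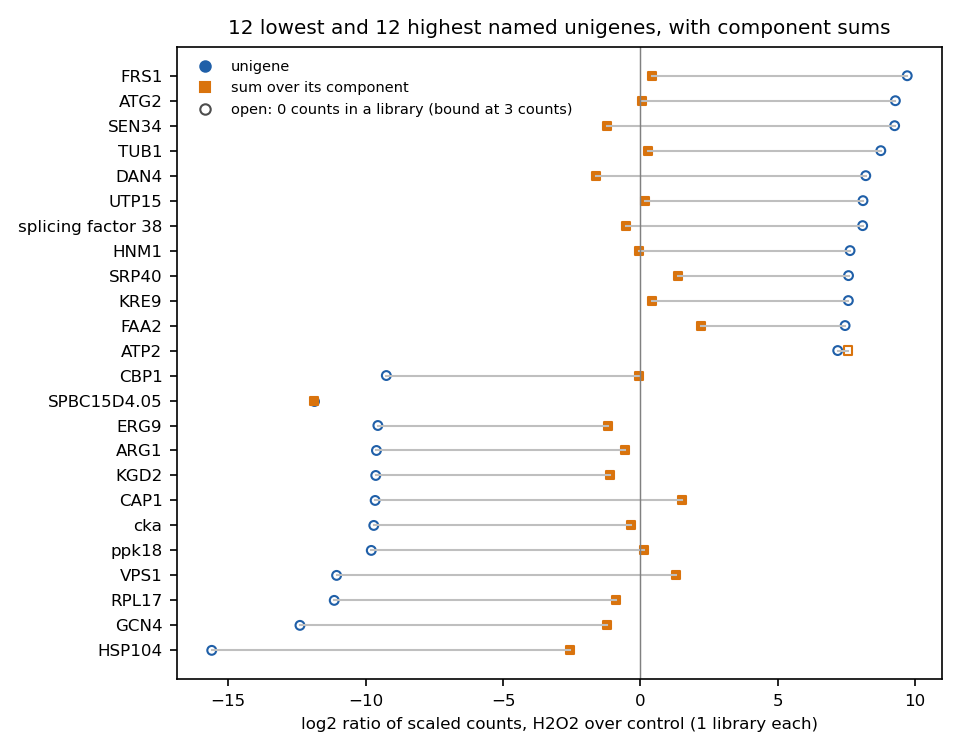
Log2 ratio of H2O2 over control (horizontal) for the 12 highest and 12 lowest named unigenes (vertical), as single unigenes (blue circles) and summed over their assembly component (orange squares). Open symbols are at 0 counts in a library and drawn at the bound from 3 counts, and 20 of the 24 sums lie within 4-fold of equality.

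Within the authors' deposited table, unigenes with an animal or plant best hit were also more abundant in the H2O2 library. Their CPM (without composition factors) was 500 against 18.2 in control. Such hits outside the table were not seen. Of 113 such unigenes, 98 were higher and 1 lower. A further 7 unigenes, with best hits sorted as neither yeast, other fungus, animal nor plant, went the other way in sum. Their CPM (without composition factors) was 3495 in H2O2 against 34013 in control, with 2 unigenes higher and 3 lower. The list of mitochondrially encoded genes, kept as a sign of RNA quality, had a median of 5.29 (3.01 with zeros at their bound, percentile 99.4), and its 12 unigenes with animal or plant hits were all higher. Its 6 yeast unigenes were lower, but 4 of them are nuclear genes matched by name, the methyltransferase NEP1 and 3 subunits of the cytochrome b-c1 complex. The other 2 are unigenes of cytochrome b (COB) in 1 component, with a log2 ratio of -2.53 in sum. The list of best hits in named bacteria, plants or animals had 20 higher and 1 lower, with a median of 4.89 (3.24 with zeros at their bound, percentile 35.04). Transposable elements and viruses held 3 unigenes, all at 0 in control, with 98 counts in H2O2 and percentile 33.4, and 1 of them is SKI2, an RNA decay helicase with a component log2 ratio of 0.05. In all, 6 of the 29 lists stood apart.

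The authors' deposited table listed 451 unigenes as higher and 547 as lower in H2O2, with an FDR of at most 0.01. All 998 had the same direction in the counts, which is no independent check because both rest on the same 2 libraries. The table held 958 (47.8%) of the 2004 size calls. In the authors' deposited table the smallest absolute log2 ratio was 2.08, and 293 of its unigenes were at 0 in a library. Of its called unigenes, 367 had a near-identical copy, and 64 of these had the opposite direction once copies were summed.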

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

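All tests in this part were chosen after the results were seen.

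Unigenes with best hits in animals summed to 5478 counts in the H2O2 library and those with best hits in plants to 3703, against 146 and 121 in control, and were picked out as a signal outside the yeast measurement and above its control level. From the control sum and the library sizes 423 counts are predicted by depth, where 9181 were found. Only unigenes in the authors' deposited table carry a best hit, however, and its smallest absolute log2 ratio was 2.08. Animal or plant hits that did not differ were not seen. That selection favours an excess, so this comparison cannot decide on depth. RNA or reads of other organisms and yeast transcripts with a wrong best hit cannot be told apart for the 113 unigenes together. The codon usage of 21.2% (14.1 to 29.9) of them fell below the lowest 5% of other unigenes of matched length. Under 15% was asked for yeast transcripts and over 50% for other organisms. The share was 5.95% (4.82 to 7.25) among 1546 other unigenes in the same range of counts. A share near 5% is built in for such unigenes, because the limit was taken from them. By best hit, 18 of 103 animal unigenes (10.7 to 26.2%) and 6 of 10 plant unigenes (26.2 to 87.8%) fell below that limit. The plant interval lies above 15%. The codon frequencies, however, were pooled over yeast unigenes, while plant hits such as ATP1, ATP2, ND5 and nuo-49 bear names of mitochondrial proteins. Yeast mitochondrial transcripts were not scored apart, so this share cannot exclude yeast transcripts for those 10 unigenes. The plant interval also reaches under 50%, so other organisms are not established for them. The animal interval spans 15%, so the animal hits stay undecided. How these counts arose was not tested further, nor was a biological explanation.

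Ribosomal protein unigenes with yeast hits were far lower in the H2O2 library, at a median log2 ratio of -6.68. Other unigenes of matched length and at least 100 control counts had a median of -0.80, and those matched on GC content had -0.12. Neither trait brought unigenes in general as low. The ribosomal protein unigenes, however, all come from the authors' deposited table, where the smallest absolute log2 ratio was 2.08. The matched unigenes were not limited to that table, so this comparison cannot decide whether length or GC content contributes. Counting on another unigene of the component is argued against for 32 unigenes, which were alone in their component with whole counts. Their median was -6.70, from -7.895 to -2.11. The component median was -6.59 over 52 components. Sums cannot change those 32, so that median could not rise above -2.11 and does not decide for the other components. Longer unigenes had a smaller difference, with a median of -5.47 above 1000 bases against -6.84 up to 1000, so reads on fused unigenes outside the named set may hide part of these transcripts. A response to H2O2 stays open as a hypothesis, and a difference between 2 single cultures or preparations cannot be excluded.

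Apart from animal and plant hits, 102 unigenes had 0 counts in one library and 100 or more in the other. All 102 had another unigene in their component, against 50.5% of 3048 other unigenes, and in 83.3% the component sum was within 4-fold between libraries. Reads divided unevenly between overlapping unigenes could produce this, but it stays open, because the test asked the 83.3% to be 2 times the 50.5%, or 101%, a bound that no share can reach. A switch between gene copies after H2O2 cannot be told apart from it in 53 unigenes (71.6% of the 74 with a near-identical partner), whose closest partner is identical over the aligned coding sequence. For the 21 with a differing partner and the 28 without one, a switch was not tested.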

How the results depend on the processing

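Sums over components or near-identical sequences, whole counts only, restriction by organism and leaving out list members with another function were chosen after seeing the data. No paired analysis was possible because each condition has 1 library, and for the same reason no library could be left out. Higher calls ranged from 501 to 1487 and lower calls from 596 to 1106 over all settings. The deposited TPM gave 1487 higher calls, whole counts only gave 571 higher and 598 lower among 2206 unigenes, and a 4-fold rule gave 501 and 596. The smaller counts follow from fewer unigenes or a stricter rule, while for TPM the cause was not tested. The standard deviation of log2 ratios was 2.74 with at least 100 counts, 2.28 with a prior count of 5 and 2.19 with component sums. The 6 lists that stood apart became 3 with at least 100 counts and 3 with a prior count of 5, and 4 with component sums, of which 3 were among the 6. With a mean for the median 8 lists stood apart, of which 3 were among the 6. The 6 stayed without members outside the list's function, which left the stress signalling list empty. Of 11 other settings, the proteasome and cytosolic ribosomal protein lists stood apart in 11, ubiquitin in 10, mitochondrially encoded genes in 7, and DNA repair and ergosterol synthesis in 5 each. DESeq2 factors and total counts shift members and random lists alike, so these settings could hardly move a list. Neither DNA repair nor ergosterol synthesis stood apart with at least 100 counts, a prior count of 5 or whole counts only. The same held with a mean and with sums over best hits or components. The share of the authors' table in the same direction was 100% with both TMM and DESeq2 factors. The table compares the same 2 libraries and its smallest absolute log2 ratio was 2.08, so this share is no independent check.

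With yeast hits only, the mitochondrially encoded list had a median of -3.93 over 6 unigenes, of which 4 are nuclear genes, so this value does not describe mitochondrially encoded genes. With component sums 13 of the 109 named unigenes took the opposite direction, and the cause was not tested. These were SEN34 at -1.23, DAN4 at -1.61, pre-mRNA-splicing factor 38 at -0.53, HNM1 at -0.065, VPS1 at 1.30, ppk18 at 0.14, CAP1 (F-actin capping) at 1.496, RPE1 at 1.24, FUM1 at 0.48, PGUG_00362 (CMR1, TRINITY_DN88_c0_g2) at -2.93, NDC80 (TRINITY_DN1408_c0_g2) at 1.10, DPB2 at -0.069 and TOM1 at -0.28. Summed over near-identical coding sequences only, DAN4 kept its direction, and VPS1, RPE1, FUM1 and DPB2 had no such copy to add. The others took the opposite direction in these sums too. Under DESeq2 factors, total counts, TPM and a prior count of 5, 0 of the 109 took the opposite direction. All 109 come from the authors' deposited table, where the smallest absolute log2 ratio was 2.08. Rescaling moved them by at most 0.83, so it could turn no direction and is no check of it. Depth limits unigenes near 20 counts, where a 2-fold difference is within counting error.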

Other observations

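The lists and genes in this part were chosen after their values were seen, so their counts and medians describe the chosen unigenes only. Genes for alternative carbon and nitrogen sources were higher in 13 and lower in 4 of 17 unigenes, with a median log2 ratio of 2.92. The alkane-hydroxylating cytochrome P450 CYP52A12 had 284 counts in control and 19989 in H2O2, a log2 ratio of 5.47 (95% interval 5.30 to 5.65). Acetyl-CoA synthetase ACS1 was 9.92-fold higher, the acetate transporter ADY2 8.82-fold and ATO2 13.3-fold. A probable quinate permease, qutD, had 28 and 8280 counts. Of 3 GAP1 permease unigenes with at least 1000 counts, log2 ratios were 2.91, 2.80 and -2.60.

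Phosphate genes were lower in 5 of 6 unigenes, with a median of -4.35. The transporter PHO84 was 25.8-fold lower, the polyphosphatase PPN1 58.2-fold and an acid phosphatase 60.1-fold, whereas the phosphodiesterase GDE1 was 14.4-fold higher. Translation factors with yeast hits were lower in 16 of 18, with a median of -3.10, and lower in 14 of 15 components. Elongation factor TEF1 had 532349 counts in control and 59559 in H2O2, a log2 ratio of -3.83 (-3.84 to -3.81). The proton pump PMA1 was 15.8-fold lower. The cell wall protein PGA62 had 253075 and 25634 counts, while the adhesin-like PGA25 had 12 and 5761. The authors' deposited table held 373 called yeast unigenes with at least 1000 counts whose component sum moved them by less than 1.5 times. Of these 125 were higher and 248 lower. Unigenes outside the table or not called were left out, so this split does not describe all abundant unigenes.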
